A study of Drosophila melanogaster with 6 samples.

How the data were processed

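Gene expression was measured in heads of 5-day-old adult male Drosophila melanogaster on Affymetrix arrays, which report the level of a transcript through sets of short probes (probe sets). The 6 arrays fell into 3 groups of 2 biological replicates, with the groups and replicates given by the sample titles and the genotypes by the labels: control flies, flies homozygous for a mutation of the microRNA gene mir-14, and rescue flies, the same mutants with miR-14 expressed in the insulin-producing cells of the brain. Heads were separated by freezing and vortexing, and total RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The titles call the replicates biological and say no more about how the flies were pooled.

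The deposited table holds 1 summarised intensity per probe set and array, made by the authors with RMA (background correction, quantile normalization between arrays and summarising of probes), as the submitters' processing notes name it; its version is not given in the sources used here. The values were on a linear scale, between 5.6 and 16778.3, with medians per array from 59.6 to 60.7, so log2 was taken before any test. The near equal medians follow from the normalization, which also removes any change of total RNA shared by all transcripts and compresses differences of dim probe sets. The table carries no detection call and no background level, so whether a dim probe set was above background is unknown here. As a rough guide, 2 dim control probe sets, AFFX-TrpnX-5_at and AFFX-r2-TagB_at, read from 8.4 to 9.6 and from 13 to 15.7 over the 6 arrays. Where a group is that dim it may lie at the floor. The size of a change from or to it may then be understated, and its rank is uncertain. The precision of every value is limited by the 2 arrays of each group. All columns of the table were used.

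Of 18952 probe sets, 183 control probe sets were left out of the tests, which left 18769. Gene names came from the platform annotation, with symbols checked against a gene table of the assembly Release 6 plus ISO1 MT. Among the tested probe sets, 13647 had 1 gene symbol (11982 genes), 402 had several and 4720 had none. The gene table held 13544 of the 1-symbol probe sets' gene identifiers, and 0 symbols changed. No gene was named from a probe set with several symbols. The gene table was used for names and for the order of genes along chromosomes, and no coordinates were taken from it.

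Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 intensity, all 6 arrays and 3 groups in the fit, two-sided). Residual degrees of freedom were 3 per probe set and the prior added 4. P-values were adjusted by the Benjamini-Hochberg method over the 18769 probe sets within each comparison, with a threshold of 0.05. The 3 comparisons were mutant against control, rescue against mutant and rescue against control. With 2 arrays against 2, a permutation test cannot pass 0.05, so no permutation p-value is given for a gene. Changes are log2 differences with the standard error (SE) of that fit. On data simulated for the mutant against control comparison, with 200 of 18769 probe sets changed, the procedure recovered 86.9% of 1.5-fold, 98.4% of 2-fold and 100% of 4-fold changes, and 8.4% of its calls were false. The simulated noise was independent and of equal spread in the 3 groups. The measured groups differed in spread, so these rates may not hold for the real arrays.

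Probe sets raised in the mutant and lowered again in the rescue were counted as the overlap of both calls. The mutant arrays enter both comparisons, so the overlap that 100 simulated sets of unchanged groups give, and the overlap of independent lists, stand beside each count. Unchanged groups yield almost no calls, so 100 further sets were simulated after the data were examined, in which the called changes of the second comparison, in units of the SD, were placed on random probe sets. These hold changes of the observed sizes that are unrelated between the comparisons but share arrays. For the restored share, no array that picked probe sets also measured it. Probe sets were picked by a change of at least 1.5-fold on 1 mutant and 1 control array. On the other arrays the summed difference between mutant and rescue was divided by that between mutant and control, over the 4 choices of arrays. The measuring mutant array enters both differences, so the share still depends on it.

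Gene lists were tested with camera (preset correlation 0.01) on 1 probe set per gene, the one with the highest mean, with adjustment over 33 lists within each comparison. Camera with the correlation estimated for each list, and fry, were run beside it. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among 1-symbol probe sets past the threshold whose groups do not overlap, the 10 largest mutant changes of each restored set, and up to 6 members with the smallest p of each list past the threshold. Members past the threshold of any other list could be named. It also takes sug, EcR, Ilp2, Ilp5, InR, foxo and bmm whatever their values, and 5 genes on each side of mir-14. A planned test of genes with miR-14 seed matches in their 3' untranslated regions was not run, since no transcript sequences were used here.

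Alternatives were an intensity trend or a robust prior in eBayes, array weights, fits of only the 2 groups compared, the replicate number as a block, quantile or cyclic loess normalization on top of the deposited values, a filter on probe sets under the 40th percentile of mean intensity, 1 probe set per gene, a threshold of 0.1, a minimum change of 1.5-fold, and leaving out each array. After the data were examined, an index of RNA quality from the array's own actin and GAPDH control probe sets (the mean of both log2 ratios of 5' to 3' signal) was added as a covariate, and a block with the mutant's replicate numbers exchanged was added.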

Results

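The 6 arrays measured 18769 probe sets in adult male heads, 2 arrays each for control flies, mir-14 mutants and rescue flies. The stated interest of the study was in genes raised in the mutant and brought back or reduced in the rescue, in which miR-14 is supplied to the insulin-producing cells, a small group of brain neurons that secrete insulin-like peptides. Replicates correlated at 0.994 in control, 0.997 in mutant and 0.998 in rescue, across probe sets, and 571, 104 and 52 probe sets differed by at least 1.5-fold between the replicates of these groups. The first principal component held 60.6% of the variance and the second 21.7%. A measure of RNA quality varied between arrays and was lowest on control replicate 2, with control and mutant arrays overlapping and both rescue arrays above the others: the ratio of 5' to 3' signal of the actin control probe sets was 0.104 and 0.0581 on the control arrays, 0.0941 and 0.137 on the mutant arrays, and 0.153 and 0.144 on the rescue arrays. For GAPDH the ratios were 0.061 and 0.0319, 0.054 and 0.071, and 0.0742 and 0.085 in the same order. The level of miR-14 itself was not analysed here.

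The comparison of mutant and control asks which transcripts differ in flies with the mir-14 mutation. The largest rise was in Alp6, an alkaline phosphatase gene, at 25.4 and 29.6 in control and 4207.6 and 3982.4 in mutant heads (7.22 ± 0.095 SE on the log2 scale, adjusted p = 3.42e-07). The α-glucosidase gene tobi rose by 6.73 ± 0.21 (adjusted p = 1.18e-05), and the odorant receptor gene Or45b by 5.50 ± 0.15 (adjusted p = 7.3e-06). Pepck2, a phosphoenolpyruvate carboxykinase gene, rose by 4.93 ± 0.15. CG16713, CG11854, the cytochrome P450 gene Cyp12d1-d, CG4962, the capsid protein gene Arc1 and the receptor gene mthl8 followed, with rises of 4.35, 4.22, 4.07, 3.97, 3.86 and 3.27. Of these, CG11854 did not pass without mutant replicate 1 (3.57, adjusted p = 0.0703). The largest fall was in the cytochrome P450 gene Cyp6a17, from 784.4 and 684.3 to 12.2 and 14.4 (-5.79 ± 0.11, adjusted p = 1.78e-06). Its mutant values were at the level of dim control probe sets, so the size of this fall is uncertain. Tektin-C, a gene of a microtubule-associated protein, changed by -4.65 ± 0.13, and Def, which encodes the antimicrobial peptide Defensin, by -3.43 ± 0.075. CG30371, Nmdmc, CG40485, CG31205, CG4408, CG9150 and hll changed by -3.41, -3.04, -3.04, -2.99, -2.93, -2.87 and -2.65.

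**Figure D1:**
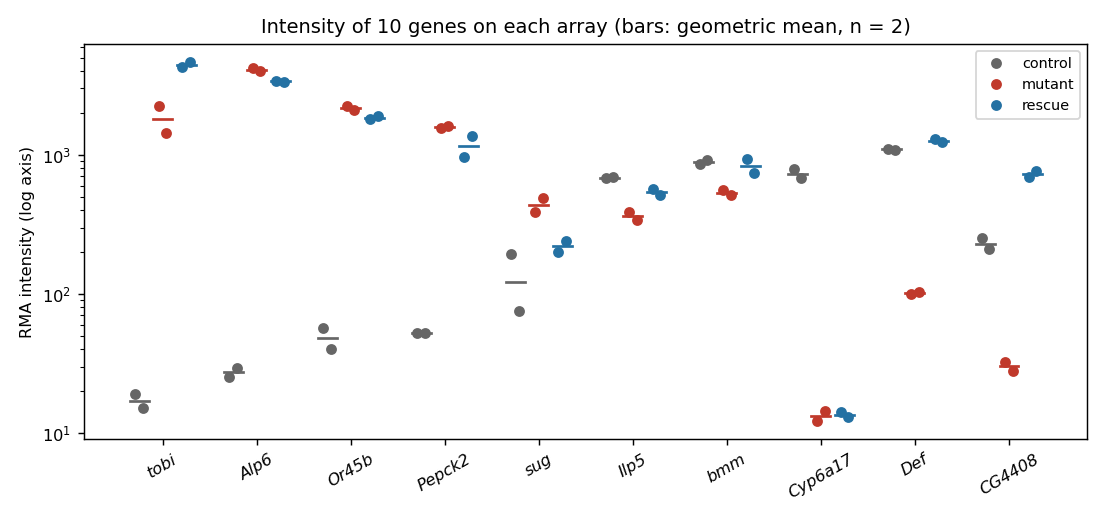
Intensity on a log axis for 10 genes on each of the 6 arrays, as points coloured by group, with bars at the geometric mean of the 2 arrays. Alp6 and Or45b are high in both mutant and rescue, and Def is low in the mutant arrays alone.

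Alp6 and Or45b are the nearest annotated neighbours of mir-14 on the same side, Or45b being the first and Alp6 the second gene in the order of the assembly Release 6 plus ISO1 MT. Ranked by rise among 11888 placed genes they were 3 and 1. The other measured genes within 5 places, CG33758, CG33757, brp, CG1888, Nt5c and Smyd4-1, had changes of -0.25, -0.15, -0.17, 0.24, -0.13 and 0.17, with adjusted p from 0.152 to 0.512. The brp value is that of its brightest probe set. Wnt2 and Not1 were not analysed here.

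**Figure D2:**
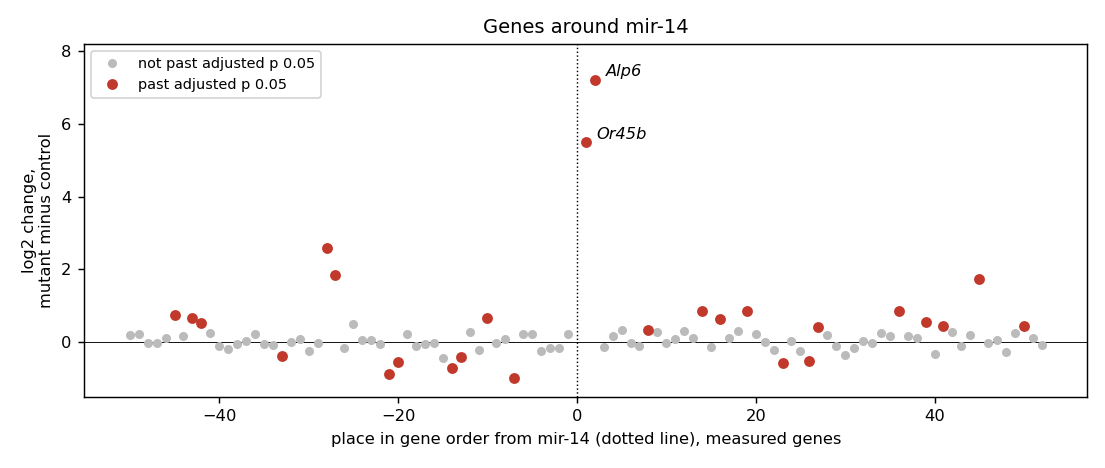
Log2 change between mutant and control (vertical axis) for measured genes in order along chromosome arm 2R, by place from mir-14 (horizontal axis, dotted line at the locus), red where past the threshold. Or45b and Alp6 stand far above their neighbours, at 5.50 and 7.22.

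Across all probe sets, 1291 were higher and 729 lower in the mutant at an adjusted p under 0.05 (limma), and 333 of them changed at least 2-fold. In 11 genes, probe sets of the same gene passed in opposite directions. The counts higher and lower were 2152 and 1877 without control replicate 1, without mutant replicate 1 they were 407 and 208, without mutant replicate 2 they were 420 and 185, and without either rescue array 715 and 347. With only mutant and control in the fit they were 715 and 347. Without control replicate 1 the only control array left is replicate 2, which had the lowest 5' to 3' ratios.

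Ilp5, an insulin-like peptide gene, fell by 0.92 ± 0.10 (adjusted p = 0.0023), from 678.8 and 688.4 to 388.1 and 337.4. Ilp2 had a change of -0.16 ± 0.092 (adjusted p = 0.307), InR, the insulin receptor gene, of 0.32 ± 0.14 (adjusted p = 0.18), and foxo, the transcription factor it restrains, of 0.34 ± 0.13 (adjusted p = 0.156). Without control replicate 1 the foxo change was 0.54, measured against control replicate 2 alone, the array with the lowest 5' to 3' ratios. Ilp3 and Thor were not analysed here. Sdr, a secreted receptor-like gene of the same list, rose by 0.84 ± 0.12. That list holds peptide genes of the insulin-producing cells, insulin-like peptides, a regulator and binding proteins. Of its 6 measured genes 1 rose (Sdr), 1 fell (Ilp5) and 4 did not pass. Of the 9 measured genes of the insulin and TOR pathway none rose or fell (limma), against 3 that rose when adjusted over the list alone and 5 higher at an unadjusted p under 0.05. Without control replicate 1, 2 of these rose. Adjusted over the list alone the peptide list had the same counts, 1 and 1. Neither list passed the camera test (adjusted p = 0.893 and 0.193).

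The gene sugarbabe (sug), a zinc finger transcription factor named before as a miR-14 target, rose by 1.85 ± 0.39 (adjusted p = 0.0267), from 193.1 and 75.7 to 386.8 and 490.6. The call did not hold without mutant replicate 1 (2.02, adjusted p = 0.115), without mutant replicate 2 (1.68, adjusted p = 0.178), or without either rescue array (1.85, adjusted p = 0.0654). The rise was 1.17 without control replicate 2 (adjusted p = 0.0086), the array with the lowest 5' to 3' ratios, and 1.15 with the 5' to 3' index as a covariate (adjusted p = 0.00552). The ecdysone receptor gene EcR, also named before as a target, had a change of 0.36 ± 0.14 (adjusted p = 0.145). Without control replicate 1 the EcR change was 0.55, measured against control replicate 2 alone. Of 5 genes reported as targets, 1 rose and 4 did not pass, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.193). The number that rose was 2 without either control array or with the covariate, and none rose without any mutant or rescue array. The triglyceride lipase gene bmm fell by 0.74 ± 0.12 (adjusted p = 0.0132), but did not pass without mutant replicate 1 (-0.80, adjusted p = 0.0714) or mutant replicate 2 (-0.67, adjusted p = 0.11). In the list of sugar genes, 6 of 28 measured rose, including tobi, sug, daw (1.01 ± 0.10) and fbp, which encodes fructose-1,6-bisphosphatase (0.98 ± 0.082), and 2 fell, Mal-B1 and Tret1-1 (7 and 5 adjusted over the list alone). Neither fall passed without 1 mutant or rescue array (adjusted p from 0.0588 to 0.149 for Mal-B1 and from 0.0605 to 0.139 for Tret1-1). The sugar genes up and down were 8 and 3 without control replicate 1, 3 up and none down without mutant replicate 1 or 2, 4 up and none down without either rescue array, and 6 and 3 without control replicate 2 or with the covariate. As a list they did not pass (adjusted p = 0.308).

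Proteasome subunits, mitochondrial ribosomal proteins and odorant genes were the 3 lists that passed the camera test between mutant and control. Proteasome subunits had a mean change of 0.16, with 7 of 40 past the threshold upward and 1 downward (camera adjusted p = 0.0145, adjusted p = 0.791 with an estimated correlation), for example Prosalpha4 at 0.51 ± 0.074 and Rpn6 at 0.49 ± 0.089. Adjusted over the list alone, 18 rose and 1 fell. Neither gene passed without mutant replicate 1 (adjusted p = 0.0721 and 0.102) or mutant replicate 2 (adjusted p = 0.0535 and 0.115). Mitochondrial ribosomal proteins had a mean of 0.11, with 6 of 69 up and 1 down, or 7 and 1 adjusted over the list alone (adjusted p = 0.0419, adjusted p = 0.791 with an estimated correlation). In this list mRpL20 rose by 0.58 ± 0.075, but did not pass without mutant replicate 2 (0.54, adjusted p = 0.0515). Odorant binding and receptor genes had a mean of -0.095, with 5 of 105 up and 14 down, or 8 and 20 adjusted over the list alone (adjusted p = 0.0325, adjusted p = 0.791 with an estimated correlation). Among these, Obp99b fell by 1.83 ± 0.11 and Obp19a fell by 1.98 ± 0.13, while Obp83g rose by 1.65 ± 0.093. The members up and down were 18 and 3 for proteasome subunits, 11 and 1 for mitochondrial ribosomal proteins and 9 and 21 for odorant genes without control replicate 1. In the same order they were 2 and 1, 2 and 1, and 4 and 13 without control replicate 2, and 2 and none, 2 and 1, and 4 and 6 without either rescue array. Without mutant replicate 1 no proteasome subunit passed, 1 mitochondrial ribosomal protein rose, and 4 odorant genes rose and 3 fell. Without mutant replicate 2 no member of the first 2 lists passed, and 4 odorant genes rose and 4 fell. With the 5' to 3' index as a covariate 3 proteasome subunits rose. The number of lists past the threshold was 5 without control replicate 1, and 0 without control replicate 2 (adjusted p from 0.0681 to 0.121 for the 3 lists) or without mutant replicate 1 (adjusted p from 0.067 to 0.0881). Mitochondrial ribosomal proteins passed without control replicate 1 but not without any other array (adjusted p from 0.0518 to 0.121), nor with the 5' to 3' index as a covariate (adjusted p = 0.0796).

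The comparison of rescue and mutant asks what miR-14 in the insulin-producing cells alters in the mutant. The largest rises were in CG4408, by 4.59 ± 0.12 (adjusted p = 1.42e-05), the odorant binding protein gene Obp99d by 4.13 ± 0.097, CG3397 by 3.96 ± 0.12, Def by 3.64 ± 0.075 and CG31205 by 3.39 ± 0.26. CG6912, CG9616, Scp2, Obp83b and 2mit rose by 2.52, 2.49, 2.30, 2.20 and 2.10. The largest falls were in CG4962 (-2.53 ± 0.094, adjusted p = 9.29e-05), CG14297 (-2.32 ± 0.22), CG18563 (-2.29 ± 0.26), CG6283, from 129.5 and 127.9 to 33.5 and 30.8, and in gol, CG14329, FarO, plu, CG4783 and CG42367. Some of these calls did not hold with 1 array left out: 2mit without mutant replicate 1 (adjusted p = 0.0887) or 2 (adjusted p = 0.11), and CG14297 (adjusted p = 0.0813 and 0.0708) and CG18563 (adjusted p = 0.132 and 0.12) without rescue replicate 1 or 2. CG4783 did not pass without mutant replicate 2 or either rescue array (adjusted p from 0.0615 to 0.16), nor FarO (adjusted p from 0.0521 to 0.0843) and CG42367 (adjusted p from 0.253 to 0.286) without any mutant or rescue array. Obp99d was 20.5 and 19.1 in control, 19.9 and 20.5 in mutant and 379.9 and 327.0 in rescue, so that its level in the rescue was above that of both other groups.

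In all, 130 probe sets were higher and 133 lower in the rescue than in the mutant. These counts were 38 and 17 without mutant replicate 1, 27 and 15 without mutant replicate 2, 33 and 9 without rescue replicate 1, and 32 and 12 without rescue replicate 2. With array weights they were 355 and 416, and with only these 2 groups 361 and 325. Control arrays enter this comparison only through the shared estimate of the spread. The median SD between replicates was 0.091 in control, 0.064 in mutant and 0.055 in rescue, so the control arrays raise that estimate.

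Ilp5 was higher in rescue than in mutant (0.58 ± 0.10, adjusted p = 0.0474) at 571.7 and 511.5. It did not pass without mutant replicate 1 (0.68, adjusted p = 0.144), mutant replicate 2 (0.48, adjusted p = 0.258), rescue replicate 1 (0.50, adjusted p = 0.361) or rescue replicate 2 (0.66, adjusted p = 0.199). The change of sug was -0.98 (adjusted p = 0.336) and that of bmm 0.64 ± 0.12 (adjusted p = 0.0688), and neither passed; without either control array both did (adjusted p = 0.0164 for sug and 0.0434 for bmm), and sug also with the 5' to 3' index as a covariate (-1.49, adjusted p = 0.00511). Ilp2, InR, foxo and EcR had changes of -0.28, -0.43, 0.050 and -0.17, with adjusted p of 0.252, 0.224, 0.924 and 0.668. The photoreceptor list, genes of the light-sensing cells, was lower in the rescue (mean -0.26, camera adjusted p = 4.4e-05, adjusted p = 0.593 with an estimated correlation), with 3 of 18 members past the threshold: inaD (-0.57 ± 0.081), trpl (-0.53 ± 0.086) and chp (-0.49 ± 0.082). Adjusted over the list alone, 11 fell. Eye pigment genes were lower as well (mean -0.28, adjusted p = 0.0124, adjusted p = 0.61 with an estimated correlation), with Pu past the threshold (-0.55 ± 0.080) and 9 of 10 not, or 4 past it adjusted over the list alone. None of inaD (adjusted p from 0.14 to 0.221), trpl (from 0.186 to 0.309), chp (from 0.245 to 0.319) and Pu (from 0.137 to 0.237) passed when 1 mutant or rescue array was left out, and no other member of either list did. Without either control array 4 members of each list fell, and with the index as a covariate 2 of each. The eye pigment list did not pass without mutant replicate 1 (adjusted p = 0.0533) or with the index as a covariate (mean -0.18, adjusted p = 0.0724). The 5' to 3' ratios of the rescue arrays were the highest of the 3 groups.

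Another 8 lists passed in this comparison, all upward. Hemocyte genes, markers of blood cells, had a mean of 0.66 (camera adjusted p = 3.17e-04, adjusted p = 0.593 with an estimated correlation), with 0 of 10 members past the threshold (limma), 0 adjusted over the list alone and 5 higher at an unadjusted p under 0.05. The mutant arrays differed in these genes, with PPO1 at 96.2 and 237.8 and NimC1 at 91.9 and 227.2, and without mutant replicate 1 the mean of the list was 0.36 (adjusted p = 0.0145). With the 5' to 3' index as a covariate it was 0.37 (adjusted p = 1.37e-04). The odorant list had a mean of 0.14 (adjusted p = 0.0137, adjusted p = 0.593 with an estimated correlation), with 9 of 105 up and 2 down, or 12 and 3 adjusted over the list alone; lush rose by 1.41 ± 0.10 and Obp83g fell by 1.22 ± 0.093. The odorant genes up and down were 5 and 1 without mutant replicate 1, 4 and 1 without mutant replicate 2 or either rescue array, and 12 and 3 without either control array. Sugar genes had a mean of 0.11 (adjusted p = 0.0176, adjusted p = 0.61 with an estimated correlation), with tobi (1.30 ± 0.21) and UGP (1.18 ± 0.19) past the threshold, or 4 up and 1 down adjusted over the list alone. The counts up and down were 4 and 1 without either control array, and 1 and 2 with the 5' to 3' index as a covariate. The call of tobi did not hold without mutant replicate 2 (0.98, adjusted p = 0.117), rescue replicate 1 (adjusted p = 0.235) or rescue replicate 2 (adjusted p = 0.268), and that of UGP without any mutant or rescue array (adjusted p from 0.0801 to 0.247). The odorant list did not pass without mutant replicate 1 (adjusted p = 0.0533), and the sugar list not without mutant replicate 2 (adjusted p = 0.092) or with the 5' to 3' index as a covariate (adjusted p = 0.0819).

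Lipid metabolism genes had a mean of 0.098 between rescue and mutant (adjusted p = 0.0176, adjusted p = 0.61 with an estimated correlation), with 0 of 25 members past the threshold, 1 up adjusted over the list alone, and 5 higher and 2 lower at an unadjusted p under 0.05. Without either control array 2 lipid genes rose. Of neuropeptides (mean 0.11, adjusted p = 0.0233, adjusted p = 0.593 with an estimated correlation), Crz rose (0.78 ± 0.084, with adjusted p from 0.0729 to 0.113 without a mutant or rescue array), and adjusted over the list alone, or without either control array, 1 rose and 1 fell. Respiratory chain genes had a mean of 0.046 (adjusted p = 0.00413, adjusted p = 0.683 with an estimated correlation), and the single member of 72 past the threshold, COX7AL, was lower (-0.69) and did not pass without any mutant or rescue array (adjusted p from 0.0765 to 0.245). Ribosomal proteins (mean 0.055, adjusted p = 0.0405, adjusted p = 0.689 with an estimated correlation) and mitochondrial ribosomal proteins (0.032, adjusted p = 0.0412, adjusted p = 0.624 with an estimated correlation) had 0 members past it, also adjusted over the list alone. At an unadjusted p under 0.05, 2 of 41 ribosomal proteins were higher, and 2 of 69 mitochondrial ones higher and 2 lower. Without mutant replicate 1, 6 lists passed in place of 10, with neuropeptides (adjusted p = 0.0533) and mitochondrial ribosomal proteins (adjusted p = 0.0729) among those that did not. Without mutant replicate 2 the lipid (adjusted p = 0.092), neuropeptide (adjusted p = 0.0501), ribosomal (adjusted p = 0.343) and mitochondrial ribosomal lists (adjusted p = 0.092) did not pass. Without rescue replicate 1, a pass was also lost for the respiratory chain (adjusted p = 0.158) and the ribosomal and mitochondrial ribosomal lists (adjusted p = 0.246 for each). With the 5' to 3' index as a covariate the lipid, neuropeptide and mitochondrial ribosomal lists did not pass (adjusted p = 0.0819, 0.113 and 0.114), and the neuropeptide mean was 0.062. The mean of the respiratory chain was 0.029 without mutant replicate 2, 0.015 without rescue replicate 1 and 0.076 without rescue replicate 2. That of ribosomal proteins was 0.086 and 0.024 without mutant replicate 1 and 2, and 0.022 and 0.088 without rescue replicate 1 and 2. For mitochondrial ribosomal proteins it was 0.010 and 0.053 without rescue replicate 1 and 2.

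**Figure D3:**
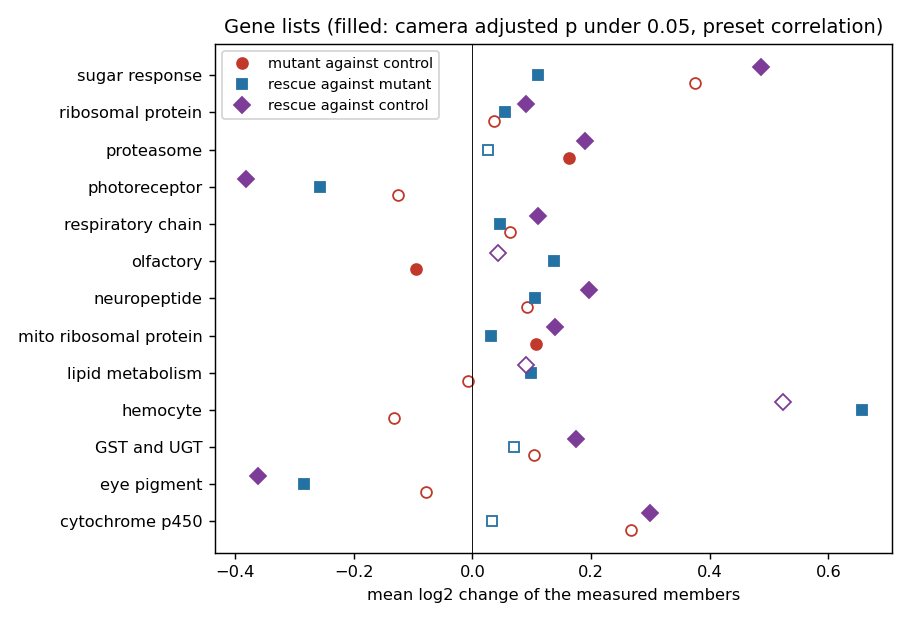
Mean log2 change of the measured members (horizontal axis) for the lists that passed camera in at least 1 comparison, with circles for mutant against control, squares for rescue against mutant and diamonds for rescue against control. Filled symbols passed at the preset correlation; GST and UGT stand for glutathione and glycosyl transferases, and the photoreceptor list lies at -0.26 and -0.38 in the comparisons with rescue.

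The comparison of rescue and control asks what differed from control flies in the rescue. The largest rises were in tobi (8.03 ± 0.21), Alp6 (6.94 ± 0.095), Or45b (5.27 ± 0.15), CG16713 (4.75), Pepck2 (4.46), Cyp12d1-d (4.27), Obp99d (4.16), CG3397 (3.86), mthl8 (3.50) and CG9377 (3.26). The largest falls were in Cyp6a17 (-5.75 ± 0.11), Tektin-C (-4.93 ± 0.13), CG30371 (-3.63), CG11893 (-3.28), CG9150, Ugt36E1, CG31038, Ctr9, pyd and HipHop. Of these, CG11893 had a change of -2.02 without control replicate 1 and of -5.98 with the 5' to 3' index as a covariate, and did not pass without either mutant array (adjusted p = 0.0654), rescue replicate 1 (adjusted p = 0.199) or rescue replicate 2 (adjusted p = 0.211). In all, 1281 probe sets were higher and 985 lower. With the index as a covariate these were 402 and 245. They were 2363 and 2516 without control replicate 1, 884 and 591 without control replicate 2, 812 and 498 without either mutant array, 352 and 145 without rescue replicate 1, and 304 and 188 without rescue replicate 2. Ilp2 fell by 0.44 ± 0.092 (adjusted p = 0.0269), a call that held without control replicate 1 and not without any other array (adjusted p from 0.0614 to 0.183) or with the index as a covariate (-0.25, adjusted p = 0.302). Ilp5 had a change of -0.34 ± 0.10 (adjusted p = 0.0726).

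Photoreceptor genes were lower in rescue than in control (mean -0.38, adjusted p = 7.4e-05, adjusted p = 0.743 with an estimated correlation), with 10 of 18 members past the threshold, or 11 adjusted over the list alone, among them trpl (-1.11 ± 0.086), Galphaq by its brightest probe set (-0.70 ± 0.088) and chp (-0.50 ± 0.082). Without rescue replicate 1 or 2 chp did not pass (adjusted p = 0.0941 and 0.105), nor did Galphaq without rescue replicate 2 (adjusted p = 0.0557). The number of photoreceptor genes that fell was 6 without control replicate 2, 2 without rescue replicate 1, 3 without rescue replicate 2, and 1 with the 5' to 3' index as a covariate. The 5' to 3' ratios were higher on both rescue arrays than on both control arrays, and with their index as a covariate chp (adjusted p = 0.139) and Galphaq (adjusted p = 0.0582) did not pass. Eye pigment genes were lower too (mean -0.36, adjusted p = 0.00909, adjusted p = 0.743 with an estimated correlation), with se, pr and Pu past it, or 5 of 10 adjusted over the list alone. The call of pr did not hold without any array but control replicate 1 (adjusted p from 0.0522 to 0.166), nor that of Pu without rescue replicate 1 or 2 (adjusted p = 0.0909 and 0.122). With the index as a covariate neither gene passed (adjusted p = 0.301 and 0.0966), nor did the list (mean -0.13, adjusted p = 0.5). Eye pigment genes that fell were 7 without control replicate 1, 1 without either rescue array or with the covariate, and 2 without any other array.

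Cytochrome P450 genes, many of them detoxifying enzymes, had a mean of 0.30 between rescue and control (adjusted p = 6.59e-04, adjusted p = 0.743 with an estimated correlation), with 23 of 83 up and 3 down, or 31 and 6 adjusted over the list alone, for example Cyp6a23 (2.44 ± 0.15) and Cyp4p2 (2.42 ± 0.11). Sugar genes (0.49, adjusted p = 0.0235, adjusted p = 0.743 with an estimated correlation) had 8 of 28 up and 1 down, or 10 and 2 adjusted over the list alone. Glutathione and glycosyl transferases (0.17, adjusted p = 0.0397, adjusted p = 0.743 with an estimated correlation) had 18 of 69 up and 2 down, or 21 and 5 adjusted over the list alone, and neuropeptides (0.20, adjusted p = 0.0456, adjusted p = 0.743 with an estimated correlation) 5 of 26 up, or 6 by the latter count. Between mutant and control the transferases were 18 up and 5 down (mean 0.10, camera adjusted p = 0.308), and between rescue and mutant 1 up and 1 down. Neuropeptide genes were 11 up and 1 down without control replicate 1, 1 up without either mutant array or with the 5' to 3' index as a covariate, and none without either rescue array. Proteasome subunits (0.19, adjusted p = 1.37e-04, adjusted p = 0.743 with an estimated correlation) had 12 of 40 up, or 19 up and 2 down adjusted over the list alone, and mitochondrial ribosomal proteins (0.14, adjusted p = 1.37e-04, adjusted p = 0.743 with an estimated correlation) 8 of 69 up and 1 down by both counts. The respiratory chain (0.11, adjusted p = 0.00112, adjusted p = 0.743 with an estimated correlation) had 3 of 72 up, and 0 adjusted over the list alone. These were 9 without control replicate 1, and none without any other array or with the covariate. Proteasome subunits had 23 up and 3 down without control replicate 1, 2 up without control replicate 2 or either mutant array, and none without either rescue array or with the covariate. Mitochondrial ribosomal proteins had 13 up and 1 down without control replicate 1, 1 and 1 without control replicate 2, 1 up without either mutant array, and none without either rescue array or with the covariate. Ribosomal proteins (0.091, adjusted p = 0.0356, adjusted p = 0.743 with an estimated correlation) had 0 of 41 past the threshold by both counts and 5 higher at an unadjusted p under 0.05 (limma), and 4 up without control replicate 1. Cytochrome P450 genes up and down were 35 and 6 without control replicate 1, 16 and 6 without control replicate 2, 17 and 2 without either mutant array, 10 and 2 without either rescue array, and 10 and 4 with the covariate. Sugar genes were 11 and 3 without control replicate 1, 6 up without rescue replicate 1, 4 up without rescue replicate 2, and 4 and 1 with the covariate. Transferases were 28 and 5 without control replicate 1, 14 and 6 without control replicate 2, 13 and 1 without either mutant array, 6 and 1 without rescue replicate 1, 4 and 1 without rescue replicate 2, and 5 and 5 with the covariate. With the 5' to 3' index as a covariate the cytochrome P450 (mean 0.15, adjusted p = 0.278), sugar (adjusted p = 0.171), transferase (mean -0.023, adjusted p = 0.908) and neuropeptide lists (mean 0.095, adjusted p = 0.584) did not pass, and the proteasome mean was 0.12. The transferase mean was below 0 there while the direction by camera stayed upward, and it was 0.28 without control replicate 1. Without control replicate 2 the sugar (adjusted p = 0.105), transferase (mean 0.067, adjusted p = 0.304) and neuropeptide lists (mean 0.13, adjusted p = 0.165) did not pass. The neuropeptide list also did not pass without rescue replicate 1 (adjusted p = 0.0704) or 2 (adjusted p = 0.0541), nor the transferase list without rescue replicate 2 (adjusted p = 0.0541). Ribosomal proteins did not pass without control replicate 1 (adjusted p = 0.102) or rescue replicate 1 (mean 0.058, adjusted p = 0.254).

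Genes raised in the mutant and reduced in the rescue, the study's stated interest, were 76 probe sets, against 9.1 expected from independent lists. Simulated unchanged groups gave a mean of 0.01, since almost nothing is called in them, and simulated groups with unrelated changes of the observed sizes, which share the mutant arrays, a mean of 11.8 (4 to 20). Part of the overlap may come from the shared mutant arrays. Of these, 55 were then not past the threshold between rescue and control, 17 were still higher and 4 lower. The 10 largest were CG4962 (3.97 then -2.53), Arc1 by its second probe set (2.42 then -0.85), CG18563 (2.27 then -2.29), CG42367, CG14297 (2.13 then -2.32), CG6283 (1.88), CG13607, CG2157, Obp83g (1.65 then -1.22) and CG13678. The Arc1 probe set with the larger rise was not among the 76, since it did not pass downward in the rescue. The falls of CG18563 (adjusted p = 0.132 and 0.12) and CG14297 (adjusted p = 0.0813 and 0.0708) did not pass without rescue replicate 1 or 2. Those of Arc1 (adjusted p from 0.0864 to 0.0983), CG42367 (from 0.253 to 0.286), CG13607 (from 0.0792 to 0.294) and CG2157 (from 0.0694 to 0.126) did not pass without any mutant or rescue array. That of CG13678 did not pass without mutant replicate 1 or either rescue array (adjusted p from 0.0571 to 0.0983). In the opposite direction 70 probe sets fell and rose again (5 from independent lists, 0.07 in unchanged groups and 7.4 with unrelated changes), of which 47 were not past the threshold against control, 13 still lower and 10 higher. Def, Nmdmc (-3.04 then 1.87), CG40485, CG31205, CG4408, hll, CG32523, CG3999, Scp2 (-2.23 then 2.30) and Obp19a (-1.98 then 1.74) were the largest. Among these, the rise of hll did not pass without any mutant or rescue array (adjusted p from 0.063 to 0.104), that of CG32523 without mutant replicate 1 or 2 (adjusted p = 0.0707 and 0.0907), and that of CG3999 without mutant replicate 2 (adjusted p = 0.0636). The counts of both kinds were 168 and 118 without control replicate 1, 162 and 134 without control replicate 2, 13 and 20 without mutant replicate 1, 12 and 16 without mutant replicate 2, 7 and 20 without rescue replicate 1, and 9 and 19 without rescue replicate 2.

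Or45b, Alp6 and Pepck2, high in the mutant, were high in the rescue too, and Cyp6a17 and Tektin-C were low in both. Of the probe sets past the threshold between mutant and control, 95.2% had the same sign between rescue and control. The shared control arrays alone give a high share: in simulated unchanged groups it was 85.7% over as many probe sets with the smallest p, and with unrelated changes of the observed sizes it was 54.2%. The simulated groups all had the same spread, whereas the median SD between replicates was 0.091 in control, 0.064 in mutant and 0.055 in rescue. A wider control spread raises the share in unchanged groups, so 95.2% is not shown to exceed what the shared control arrays give. In both comparisons 811 were higher and 404 lower, with 14 in opposite directions. Independent lists would share 88.1 and 38.3, and simulated groups with unrelated changes shared 88.9 and 43. Unchanged groups, in which almost nothing is called, gave a mean of 0.05 in the same direction. The covariance of both changes was 0.103, against 0.007 in simulated unchanged groups, and part of the overlap may come from the shared control arrays. The restored share averaged 17.2% over the 4 choices of arrays (0.7% to 28.3%), 9.3% for probe sets raised in the mutant (-8.7% to 18.5%) and 33% for those lowered (16.4% to 51.7%).

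**Figure D4:**
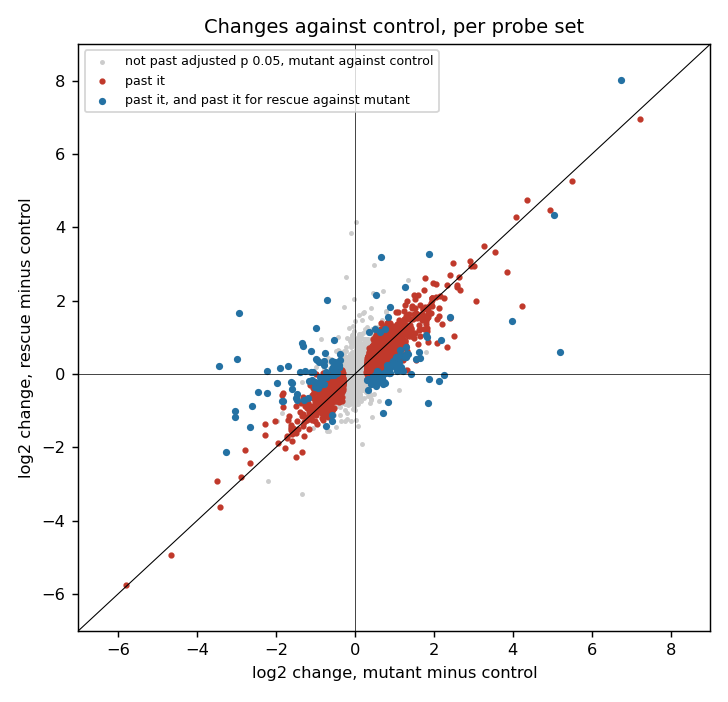
Log2 change between rescue and control (vertical axis) against that between mutant and control (horizontal axis) for 18769 probe sets, with the diagonal drawn. Red points passed the threshold between mutant and control, blue points also passed it between rescue and mutant, and 95.2% of the red and blue points together have the same sign on both axes, against 85.7% of as many probe sets picked in simulated unchanged groups that share the control arrays. The simulated groups had equal spread, while the control replicates varied more than the others, so 85.7% is likely too low.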

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

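Of the tests below, those with the RNA index as a covariate, that on Or45b and Alp6, that of the share on chromosome 3, the windows of 25 and 100 genes on each side and the bootstrap interval were chosen after the result was seen. Some control probe sets, left out of the comparisons, were above the control arrays in the mutant or rescue arrays, without overlap and at an adjusted p under 0.05. AFFX-Dm-K01486-1_at was higher by 0.47 in the rescue than in control and by 0.69 than in the mutant (adjusted p = 0.0219 and 0.0228), at 21.2 and 22.1 in the rescue; its target is not named in the tables used here, so whether it detects a transgene of these flies is not known. AFFX-Dros-ACTIN_3_at was higher by 0.68 in mutant and 0.38 in rescue, and AFFX-Dros-ACTIN_M_f_at by 0.34 and 0.42. AFFX-Dros-GAPDH_3_at was higher by 0.47 in mutant and 0.43 in rescue, and AFFX-Dros-GAPDH_M_at by 0.71 and 0.84. For actin 5C, AFFX-r2-Dros-Act5C-3_s_at was higher by 0.50 and 0.45, AFFX-r2-Dros-Act5C-M_s_at by 0.66 and 0.73. In the rescue, AFFX-r2-Dros-Act5C-5_at was higher by 1.39 and AFFX-r2-Dros-Act5C-5_x_at by 1.44. The mutant arrays were above the control arrays in both as well, by 1.04 and 1.10, without passing (adjusted p = 0.0936 and 0.11), and the difference between rescue and mutant did not pass either (0.34 for each, adjusted p = 0.731 and 0.769). AFFX-r2-Dros-GAPDH-3_a_at was higher by 0.58 and 0.66, AFFX-r2-Dros-GAPDH-3_at by 0.39 and 0.60, and AFFX-r2-Dros-GAPDH-M_a_at by 0.81 and 1.04.

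Most probe sets past the threshold between mutant and control had the same sign between rescue and control, Or45b and Alp6 next to mir-14 among them. As said above, this share is not shown to exceed what the shared control arrays give. A lower 5' signal in control is one candidate cause, lowest on control replicate 2 while control replicate 1 lay between the mutant arrays. With the index as a covariate at least 0.90 of the median change of the 1215 probe sets called alike was left (0.64 to 0.59 for mutant, 0.65 to 0.58 for rescue, against control). The 1215 were picked on these arrays by calls that favour small differences between replicates, and the covariate's effect is estimated from those differences. A small correction was thus likely beforehand, so it cannot decide whether the 5' signal was the whole cause. Or45b and Alp6 stayed at least 4.92 above control, which argues against it as the whole cause for these 2 genes. Calls of the 1215 fell to 963 in the mutant and 459 in the rescue. The median SE was 0.10 in both fits for the mutant and went from 0.10 to 0.13 for the rescue. The covariate also takes a residual degree of freedom, and what ended the calls was not separated. Mutant replicate 1 minus control replicate 1, with similar indices, gave a median of 0.58, which decides nothing, since the probe sets were picked on these arrays too. A strain difference linked to the mutation is a candidate explanation for the region: without Or45b and Alp6, 24% of the 100 genes around mir-14 changed between mutant and control, against a median of 13%, at percentile 99.7 of 11127 windows elsewhere (98.5 with 25 and 98.1 with 100 genes on each side). Cyp4p2 and trpl, named above, are among these 100 genes. For chromosome 2 as a whole, the measure was the share of genes called alike in mutant and rescue against control. It was 9.2% there and 7.6% on the other chromosomes, a ratio of 1.21 (one-sided permutation p = 0.16 from 10000 circular shifts). This leaves linkage open for the whole chromosome. A role of miR-14 outside the insulin-producing cells was not tested.

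Probe sets that differed between rescue and mutant were more frequent on chromosome 3, at 2.41% of its placed genes against 1.17% elsewhere, a ratio of 2.05, while the small chromosome 4 had a higher share, 5 of 65 genes (7.69%). A strain difference on chromosome 3, such as a transgene's background would bring, is a candidate explanation. Permutation by circular shifts gave p = 0.041 for chromosome 3 and p = 0.074 for the highest of X, 2 and 3, which allows for its being picked among these after its share was seen and leaves out chromosome 4, so chance is not excluded. The densest window of 100 genes on chromosome 3 held 8 calls against a median of 7 in random placements (permutation p = 0.48), which does not locate a region. Of 115 placed genes changed in the mutant and changed back in the rescue, 70 lay on chromosome 3, which is no separate evidence since they are part of the same calls, and an effect of miR-14 in the insulin-producing cells stays open as the biological explanation, untested.

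The photoreceptor list was lower in the rescue than in the mutant by camera at the preset correlation (adjusted p = 4.4e-05), but did not pass with an estimated correlation (adjusted p = 0.593) or by fry (adjusted p = 0.054). A higher 5' signal in the rescue arrays is a candidate cause. With the index as a covariate the mean change was -0.23, against -0.26 without it. The covariate's effect is estimated from differences between replicates. Their index values lay far apart in control (-3.649 and -4.539) and close together in rescue (-3.231 and -3.173). Both rescue arrays also lay above all others, so this fit cannot decide whether the 5' signal was the whole cause. Less eye material in the rescue heads may account for a fall shared by most members, 15 of 18 being below 0. Their changes ranged from -0.57 to 0.10, with an SD 2.23 times the root mean square SE (95% bootstrap interval 1.58 to 2.66), so that the interval lies above the bound of 1.5 set for an even fall but includes the bound of 2 set for an uneven one, and this stays open. A biological effect of the rescue on these genes was not tested separately.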

How the results depend on the processing

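The RNA index as a covariate and the exchanged block were chosen after the data were examined; the other alternatives were set before. The cause of each shift was not tested except where fewer arrays or a stricter rule gives it. For rescue against mutant, the fits with and without the control group differ only in the estimated spread and its degrees of freedom. No count moved by over 1.5 times with an intensity trend, a robust prior, cyclic loess, 1 probe set per gene or the exchanged block. The restored share stayed within its spread at 22.1 when picked at 2-fold and 16.8 with cyclic loess or the dim filter. The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.255 for control and mutant, -0.188 for control and rescue and 0.004 for mutant and rescue. The replicate block gave 859 higher and 418 lower for mutant against control, 76 and 54 for rescue against mutant, 846 and 533 for rescue against control, and 39 and 44 restored. The exchanged block gave 1166 and 678, 115 and 124, 1213 and 935, and 69 and 66. Array weights gave 355 and 416 for rescue against mutant and 178 and 116 restored. Only the 2 groups compared gave 715 and 347, 361 and 325, and 812 and 498. A minimum of 1.5-fold gave 609 and 311 for mutant and 696 and 374 for rescue against control. At an adjusted p under 0.1, 1337 were lower in the mutant, 254 higher and 288 lower between rescue and mutant, 1882 lower between rescue and control, and 169 restored from a rise. With the covariate, rescue against control had 402 and 245. Lists past the threshold between mutant and control were 1 after quantile normalization and 1 without dim probe sets, and with estimated correlations 0, 0 and 0 in the 3 comparisons. By fry, lists past it were the ecdysone list between rescue and mutant (adjusted p = 0.0366) and the photoreceptor list between rescue and control (0.0399).

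Leaving out each array in turn leaves 1 array in a group, assumed to vary like the others. Mutant against control then ranged from 407 to 2152 higher and 185 to 1877 lower, rescue against mutant from 27 to 361 and 9 to 325, rescue against control from 304 to 2363 and 145 to 2516, and the restored counts from 7 to 168 and 16 to 134. Lists past the threshold ranged from 0 to 5 for mutant against control and from 6 to 15 for rescue against mutant. Between rescue and control, values under the threshold turned sign: EcR ranged from -0.005 to 0.38, InR from -0.298 to 0.086 and bmm from -0.27 to 0.078. With the covariate EcR was at -0.188, bmm 0.045, cd 0.007 and sug -0.344 between rescue and control, and foxo -0.089 between rescue and mutant. Signal over background is unknown here, which limits dim probe sets. The planned miR-14 seed test was not run.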

Other observations

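Some other gene groups held members past the threshold without passing as lists. Of 80 measured cuticle genes, 11 rose in the mutant, for example Cpr51A (2.07 ± 0.13) and Cpr49Ae (1.85 ± 0.13), and 6 fell between mutant and rescue, including Cpr92F (-1.13 ± 0.092, not past the threshold without mutant replicate 2 or rescue replicate 1, adjusted p = 0.0612 and 0.0521) and Cpr62Bc (-0.98 ± 0.11, not past it without any mutant or rescue array, adjusted p from 0.088 to 0.123); camera adjusted p were 0.874 and 0.161. Without 1 array the cuticle genes up and down in the mutant were 13 and 4 (control replicate 1), 10 and 1 (control replicate 2), 6 and none (mutant replicate 1), 7 and none (mutant replicate 2) and 9 and none (either rescue array). With the RNA index as a covariate they were 10 and 2. Between mutant and rescue 1 fell without mutant replicate 1 or rescue replicate 2, and none without mutant replicate 2 or rescue replicate 1. Adjusted over the list alone, 12 rose and 2 fell in the mutant and 9 fell between mutant and rescue; the list's mean in the mutant was 0.10 and its median -0.045. Of 13 fat body genes 1 rose and 3 fell in the mutant, or 2 and 4 adjusted over the list alone (list adjusted p = 0.15). Those that fell were fit (-2.29 ± 0.13), Obp99b and the larval serum protein gene Lsp2 (-0.76 ± 0.081). Obp99a rose (0.50 ± 0.12, adjusted p = 0.0457), a call that held without control replicate 1 and not without any other array (adjusted p from 0.0976 to 0.224) or with the RNA index as a covariate (adjusted p = 0.121). Between mutant and rescue 2 rose and 0 fell (limma), with 4 higher and 2 lower at an unadjusted p under 0.05, and 4 and 2 adjusted over the list alone (list adjusted p = 0.0704). The counts were 3 and 1 without either control array. The 2 that rose were Lsp2 (0.67 ± 0.081) and Obp99b, of which Lsp2 did not pass without any mutant or rescue array (adjusted p from 0.0765 to 0.16), nor Obp99b without mutant replicate 2 or either rescue array (adjusted p from 0.0684 to 0.0838). Of 11 clock genes only per passed in the mutant, where it rose by 0.54 ± 0.086, and between mutant and rescue, where it fell by 0.68 ± 0.086 (list adjusted p = 0.922 and 0.106). Adjusted over the list alone 1 rose in the mutant, and between mutant and rescue 1 rose and 4 fell. Without control replicate 1, 2 rose and 1 fell in the mutant. The rise did not pass without mutant replicate 1 or 2 (adjusted p = 0.0853 and 0.0709), and the fall not without any mutant or rescue array (adjusted p from 0.0916 to 0.174). Of 25 neuron and synapse genes 1 rose and 3 fell in the mutant, also adjusted over the list alone (list adjusted p = 0.486). These were 4 and 2 without control replicate 1, 1 and 1 without mutant replicate 1 or 2, and 1 and 5 with the RNA index as a covariate. In the tyrosine hydroxylase gene ple the mutant was higher by 0.65 ± 0.075, and the dopa decarboxylase gene Ddc was lower by 0.82 ± 0.095 there.

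Markers of body material that could enter a head sample did not pass as lists between mutant and control: gut (adjusted p = 0.193), testis and accessory gland (0.155) and female genes (0.4). The vacuolar proton pump, cell death, heat shock and Hedgehog lists did not pass either in that comparison (adjusted p = 0.65, 0.839, 0.386 and 0.193).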
